A study of Mus musculus with 198 samples.

How the data were processed

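RNA was extracted from whole tissues with a Qiagen 96-well kit and treated with DNase, and stranded total RNA libraries were made from 100 ng of RNA with 12 PCR cycles, per the labels' protocols. Per the submitters' processing notes, reads were checked with FastQC 0.11.5 and quantified with Salmon, and the build named is mm10. The authors deposited whole-number counts for 56332 genes in 22 libraries of each of 9 tissues, of which 47712 carry Ensembl and 8620 carry UCSC identifiers and 498 names are shared by more than 1 identifier. How Salmon's estimates became whole numbers, the annotation, any filter and the strand setting are not given in the sources used here. Total RNA libraries keep ribosomal RNA that was not removed, and 9 features with a mean share of at least 0.9 percent held most counts, so the depth for other genes is far below the total. Counts of near-identical genes (globins, ribosomal protein pseudogenes, P450 paralogs, MHC and immunoglobulin genes) can be split between copies and are uncertain. Coordinates are from GENCODE vM21 on mm10, in which 47462 of the Ensembl identifiers were found, 41889 with the same version.

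Groups were taken from the labels, and each mouse was 1 replicate. The same mice gave all tissues, which pairs tissues but not arms, since no mouse was in both. The correlation within a mouse over tissues was 0.013. In each tissue the deposited counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM, filterByExpr, sex as covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The sex by treatment term was tested in the same way. Over the tissues, limma 3.58.1 tested each mouse's mean log2 CPM (prior count 2) for genes passing the filter in every tissue, and limma-voom tested whether effects differed between tissues. All tests were two-sided, and permutation tests drew 100000 resamples of the labels within sex. CPM values were computed here from the deposited counts.

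The 49 gene lists were fixed before the data were examined, and those with 5 or more tested members were tested with camera on voom values at a preset inter-gene correlation of 0.01, adjusted over all 243 list and tissue pairs. Genes were named by a rule fixed at the same time. In each tissue these were up to 10 genes per direction past the threshold with a mean of at least 1 CPM, an official symbol and the same direction in both sexes. Where none passed, the 3 genes per direction with the smallest p were given as values. Pappa, Igf1, Igfbp4, Igfbp5, Col1a1, Col1a2 and Col3a1 were named wherever tested, and up to 4 members with the smallest p for each list described. Some genes that this rule takes are not reported here. Names that are transcript identifiers were treated as bare identifiers.

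Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE scaling, no low count filter, sex left out, 2 surrogate variables (sva 3.50.0), each mouse or tissue left out, genes passing in 5 or more tissues, the mouse as a block, other numbers of tissues for shared genes and an estimated inter-gene correlation. Chosen after seeing the data were fits without the 5 libraries in doubt, without the abundant features and with sample quality weights, permutation of list means, gene lists without each mouse, each tissue's own collagens, and the tests of Igfbp5 and of all lists over the tissues. A library was in doubt where the markers of its tissue lay more than 2 below the tissue median on the log2 scale or fewer than 1000 genes had 10 or more counts.

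The total count per library had a median of 8950258, and the count outside the abundant features one of 1099966.5. The tests were tested on simulated data with known changes. Of genes changed 1.5-fold and 2-fold, 77.1% and 95.2% were recovered in bone marrow, 61.9% and 87.5% in gonadal fat, 22.9% and 70.3% in heart, 69% and 96.8% in kidney, 62.2% and 93.4% in liver, 50.6% and 92.2% in lung, 27.4% and 90.2% in skin, 73.8% and 95.3% in spleen and 19% and 73% in subscapular fat. Over the tissues 98.8% of 1.5-fold changes were recovered. Each simulation held many changed genes at once, in gonadal fat 84 at 1.5-fold, 64 at 2-fold and 51 at 4-fold. Adjustment over all genes is stricter where fewer genes change, so these rates cannot exclude 2-fold changes in the real data. There, Arg1 in gonadal fat did not pass at a log2 fold change of 2.79 ± 0.75 (SE, edgeR, adjusted p = 0.973). The test of differences between tissues recovered 89.5% of 4-fold changes with 72 false calls among 6295 genes, so it can call too many genes. Smaller changes were not simulated for that test, so how many of them it misses is not known. Tables were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and figures drawn with matplotlib 3.10.9.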

Results

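RNA-seq was carried out on 9 tissues of 22 C57BL/6 mice that had received control treatment or an antibody against PAPP-A for 17 weeks. PAPP-A is a secreted metalloproteinase that cleaves the insulin-like growth factor (IGF) binding proteins IGFBP-4 and IGFBP-5 and so frees IGF near cells. The control group held 12 mice and the anti-PAPP-A group held 10, with 6 and 5 of each sex. Skin, bone marrow, spleen, liver, lung, kidney, heart and the gonadal and subscapular fat were taken from every mouse, which gave 22 libraries per tissue. The question put by the design was which genes differ between the arms in each tissue, and the study's title points to mesenchymal stromal cells, the connective-tissue cells that make collagen.

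Total counts ran from 4138419 to 19517950 per library with a median of 8950258. Most of these counts came from 9 features, chiefly ribosomal RNA and features that overlap it (Lars2, Gm42418, AK155692, NR_046233 and mt-Rnr2 lead them), which took 47.4% to 99.5% of a library and 87.4% at the median. The count left for all other genes was 33377 to 4694597 per library with a median of 1099966.5. In lung this usable depth was lower in treated mice by a mean log2 difference of -0.71 (two-sided permutation test, p = 0.00291, adjusted p = 0.0262 over the 9 tissues). In no other tissue did the difference in depth pass (adjusted p of 0.597 or above), with estimates from -0.444 in skin to 0.357 in bone marrow.

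**Figure D1:**
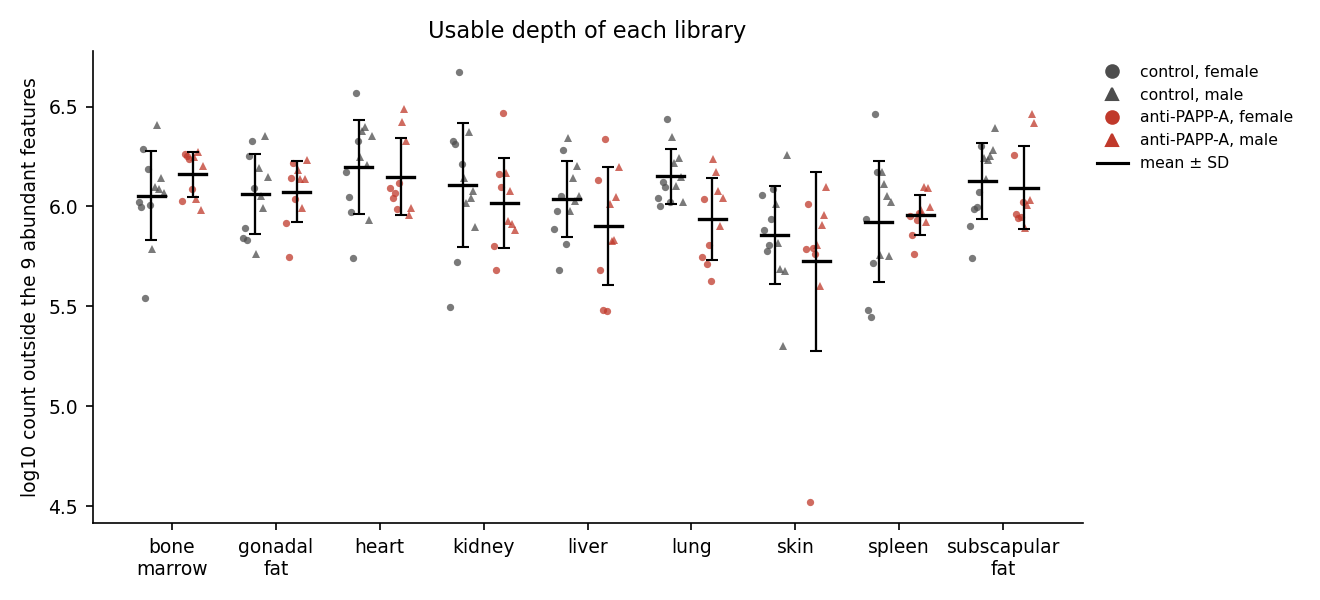
Usable depth of each library, as log10 of the count outside the 9 abundant features, by tissue, where points are mice (grey control, red anti-PAPP-A, circles female, triangles male) and black lines the mean ± SD of each arm. The lowest library is the treated female skin library of mouse 36 at 33377 counts, and lung is lower in the treated arm.

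Xist and Y-linked genes matched the sex label of every library. Xist stood at 239.7 CPM or more in female libraries and at 21.8 or less in male ones, and the Y-linked genes at 159.9 or more in males and 4.7 or less in females. In 5 libraries the markers of the labelled tissue lay far below the tissue's median. The library labelled lung of control male mouse 68 had a lung epithelium mean of 1.37 log2 CPM against a median of 10.22 and an adipocyte mean of 9.37. Cardiomyocyte means in heart were 7.57 in control female mouse 22, which had an adipocyte mean of 9.24, and 8.09 in treated male mouse 56, which had a cell cycle mean of 6.73, against a median of 10.98. Gonadal fat of treated male mouse 58 had an adipocyte mean of 7.29 against 9.78 and a macrophage mean of 8.71. The skin library of treated female mouse 36 had a keratinocyte mean of 7.29 against 10.5 and only 308 genes with 10 or more counts.

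In bone marrow Igfbp5, which encodes the IGF-binding protein that PAPP-A cleaves along with IGFBP-4, fell in treated mice. Its level was 9.54 ± 3.61 CPM (SD, n = 12) in control and 3.25 ± 1.13 CPM (n = 10) in treated mice, a log2 fold change of -1.56 ± 0.20 (SE, edgeR quasi-likelihood F-test, adjusted p = 0.00053). All 10 treated mice lay below the control median, and the log2 fold change was -1.17 in females and -1.97 in males (interaction adjusted p = 1). Igfbp5 (ENSMUSG00000026185.8) lies on chromosome 1 from 72857932 to 72874884 on the minus strand (mm10) and has 4 exons. It was the 1 gene of 12891 tested in marrow that passed by edgeR, by DESeq2 and by limma-voom, and 905 genes had an unadjusted p under 0.05. Adjusted over the list alone, of the 8 members of the PAPP-A and IGF axis tested in marrow, Igfbp5 had an adjusted p of 3.29e-07, while that list as a whole was not called (adjusted p = 0.203).

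**Figure D2:**
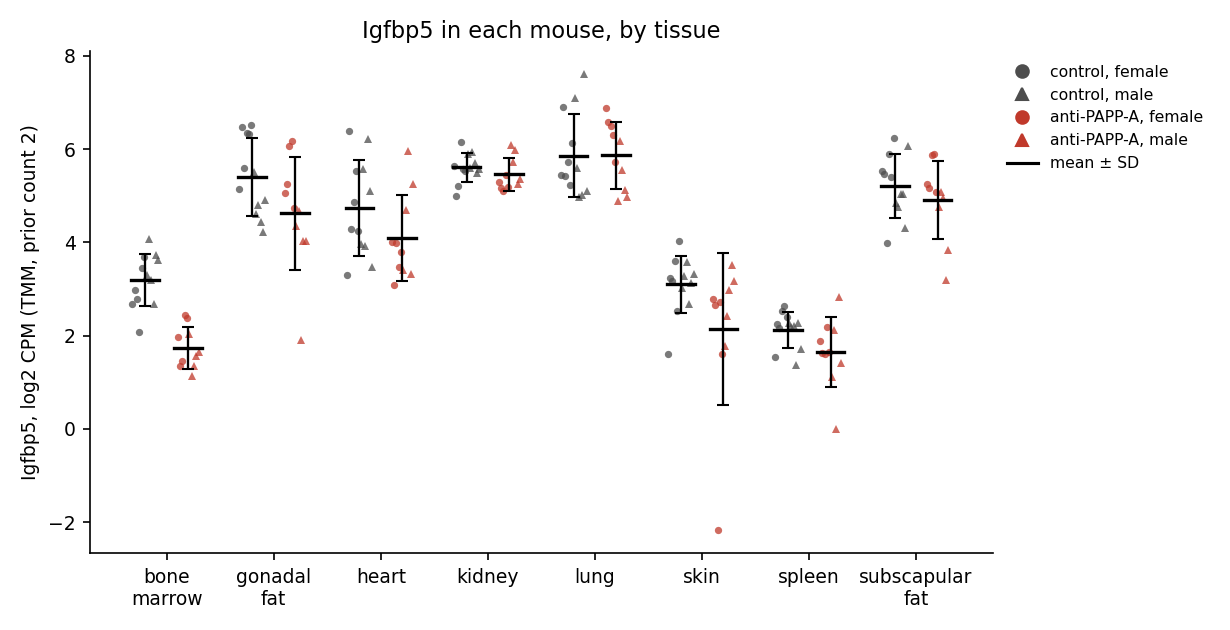
Igfbp5 in log2 CPM for each mouse in the 8 tissues where it passed the count filter, where points are mice (grey control, red anti-PAPP-A, circles female, triangles male) and black lines the mean ± SD of each arm. Bone marrow is the tissue where the difference passed the test (log2 fold change -1.56), and the estimates of the other 7 tissues, down to -0.77 in heart, did not.

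Fixed gene lists were tested in each tissue as groups with camera at a preset inter-gene correlation, and 73 of 243 list and tissue pairs passed, 18 higher and 55 lower in treated mice. With a correlation estimated from the data 0 of the 243 passed, with fry 0 passed, and 23 of 243 had an unadjusted p under 0.05 in a permutation test of list means, which called 0 (lowest adjusted p = 0.187). When each mouse in turn was left out of all tissues, 35 of the 73 calls were kept in every fit that tested the list and 38 were lost in at least 1. These fits were chosen after the data were seen. No member of a called list passed over all genes tested in its tissue, so members are said to have risen or fallen only where they passed when adjusted over the list alone, and all others are given as values. List values are the median log2 difference over the members tested on the voom scale. Values of single members are edgeR log2 fold changes, and for some lists the edgeR median differs widely from the voom median.

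Neutrophil genes were lower in treated marrow. The median was -0.27 over 12 members (adjusted p = 2.67e-07 and adjusted p = 0.509 with an estimated correlation). Adjusted over the list alone, 5 of the 12 fell and 7 did not pass. Among the former were Ly6g (-0.50 ± 0.13, SE), the calprotectin subunits S100a8 (-0.55 ± 0.16) and S100a9 (-0.51 ± 0.17), and the antimicrobial peptide gene Camp (-0.51 ± 0.18). Haematopoietic progenitor genes were higher, with a median of 0.19 over 7 members (adjusted p = 0.0026 and adjusted p = 0.242 with an estimated correlation). Of these the cytokine receptor gene Flt3 (0.41 ± 0.15) and the homeobox gene Meis1 (0.35 ± 0.13) rose when adjusted over the list alone and 5 did not pass, Kit at 0.28 ± 0.12. In cholesterol synthesis and uptake, at a median of -0.17 over 13 members (adjusted p = 0.0026 and adjusted p = 0.509 with an estimated correlation), the sterol oxidase gene Msmo1 fell (-0.56 ± 0.13) and 12 members did not pass. Oxidative phosphorylation (-0.19 over 17 members, adjusted p = 3.06e-05 and adjusted p = 0.612 with an estimated correlation) and ribosomal proteins (-0.21 over 22, adjusted p = 4.39e-05 and adjusted p = 0.681 with an estimated correlation) were lower with 0 members passing. Examples were Cox5a at -0.39 ± 0.15 and Rpl32 at -0.35 ± 0.16. The same held for plasma cell genes (-0.42 over 6, adjusted p = 0.0048 and adjusted p = 0.612 with an estimated correlation), Jchain at -0.42 ± 0.20. Marrow collagens were lower with 0 passing (-0.25 over 5, adjusted p = 0.0288 and adjusted p = 0.584 with an estimated correlation), Col5a1 at -0.46 ± 0.17 and Col1a1 at -0.21 ± 0.20. The collagen (-0.15, adjusted p = 0.103) and plasma cell (-0.17, adjusted p = 0.168) lists were not called with 2 surrogate variables. Nor were collagens without control mouse 11 or 68 or treated mouse 6, 23, 33 or 41 (-0.31 to -0.19, adjusted p = 0.0501 to 0.0701), or plasma cell genes without treated mouse 58 (-0.28, adjusted p = 0.0553).

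In gonadal fat erythroid genes, chiefly globins, were lower and macrophage genes higher, while collagens and lipogenic genes were lower. The erythroid median was -0.67 over 5 members (adjusted p = 8e-08 and adjusted p = 0.425 with an estimated correlation), and 4 fell adjusted over the list alone while 1 did not pass. These were the globin genes Hba-a2 (-0.71 ± 0.20), Hbb-bs (-0.64 ± 0.20), Hbb-bt and Hba-a1. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so counts within each pair cannot be read as separate genes. Smooth muscle genes had a median of -0.33 over 7 members (adjusted p = 0.00182 and adjusted p = 0.509 with an estimated correlation), where Myl9 (-0.75 ± 0.19) and Acta2 (-0.49 ± 0.18) fell adjusted over the list alone and 5 members did not pass. Collagens had a median of -0.18 over 17 members with 0 passing (adjusted p = 0.000298 and adjusted p = 0.65 with an estimated correlation), Col5a1 at -0.39 ± 0.15 and Col18a1 at -0.26 ± 0.11. Lipogenic genes had a median of -0.49 over 12 with 0 passing (adjusted p = 0.00052 and adjusted p = 0.67 with an estimated correlation), Scd1 at -0.91 ± 0.42.

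Macrophage genes in gonadal fat had a median of 0.34 over 11 members with 0 passing (adjusted p = 0.00219 and adjusted p = 0.696 with an estimated correlation), Lyz2 at 0.61 ± 0.25 and Itgam at 0.73 ± 0.31. Hepatocyte genes had a median of -1.54 over 5 members (adjusted p = 0.00219 and adjusted p = 0.545 with an estimated correlation). Adjusted over the list alone, 4 fell, among them the plasma protein genes Apoa1 (-1.98 ± 0.73), Ahsg (-1.71 ± 0.69) and Alb (-1.48 ± 0.70). Arg1, an arginase gene that macrophages also express, rose (2.79 ± 0.75). Plasma cell genes were higher (0.60 over 5, adjusted p = 0.0026 and adjusted p = 0.509 with an estimated correlation), Prdm1 rising adjusted over the list alone (0.78 ± 0.27) and 4 not passing, Igkc at 0.88 ± 0.40. Beside them, B cell means in gonadal fat were highest in treated mouse 23 (4.97 log2 CPM), control mice 4 (3.71) and 68 (3.52) and treated mouse 36 (3.45), against medians of 1.69 in control and 1.97 in treated mice. Immediate early genes were higher (0.26 over 9, adjusted p = 0.0476 and adjusted p = 0.67 with an estimated correlation), Junb rising (0.80 ± 0.26) and 8 not passing, Atf3 at 0.94 ± 0.37. Ribosomal proteins (0.12 over 22, adjusted p = 3.06e-05 and adjusted p = 0.691 with an estimated correlation, Rps18 at 0.22 ± 0.12) were higher with 0 members passing. So were ER stress genes (0.10 over 12, adjusted p = 0.0393 and adjusted p = 0.65 with an estimated correlation, Pdia6 at 0.25 ± 0.14). Adipocyte genes (-0.27 over 12, adjusted p = 0.00628 and adjusted p = 0.753 with an estimated correlation, Adipoq at -0.23 ± 0.28) were lower with 0 passing. Matrix glycoproteins were lower too (-0.17 over 25, adjusted p = 0.0128 and adjusted p = 0.696 with an estimated correlation, Eln at -0.64 ± 0.26 and Fn1 at 0.46 ± 0.29), again with 0 passing.

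By edgeR 0 of 11993 genes passed in gonadal fat (609 at an unadjusted p under 0.05), and DESeq2 and limma-voom called 0. The smallest p values belonged to Coro2a (0.72 ± 0.19), Cytip (0.98 ± 0.26) and Stk10 (0.56 ± 0.15) among genes with higher means. Among those with lower means they belonged to Glcci1 (-0.73 ± 0.18), Myl9 and Med9 (-0.48 ± 0.12), all at an adjusted p of 0.973. Without the libraries in doubt, in this tissue that of mouse 58, low in adipocyte and high in macrophage genes, the adipocyte (-0.04, adjusted p = 0.64), macrophage (0.12, adjusted p = 0.0807), matrix (-0.08, adjusted p = 0.132), ER stress (0.06, adjusted p = 0.286) and immediate early (0.13, adjusted p = 0.43) lists were no longer called. The collagen median then was -0.11 (adjusted p = 0.011), and Arg1 in gonadal fat was at 1.18 ± 0.62. The matrix list was also lost without control mouse 68 (-0.12, adjusted p = 0.109), and the adipocyte list without treated mouse 33 (-0.16, adjusted p = 0.0837) or control mouse 37 (-0.18, adjusted p = 0.0786). Of the 22 fits without 1 mouse, 13 lost the ER stress list and 14 the immediate early list. With 2 surrogate variables the adipocyte list was called higher (0.17, adjusted p = 0.000455), the ribosomal median reversed without a call (-0.02, adjusted p = 0.771), and the macrophage median was 0.06 (adjusted p = 0.799). The lipogenic (-0.01, adjusted p = 0.863), ER stress (0.04, adjusted p = 0.862) and immediate early (0.10, adjusted p = 0.145) lists were then not called.

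In heart collagens were lower as a group, with matrix genes and the PAPP-A and IGF axis. The collagen median was -0.34 over 16 members with 0 passing adjusted over the list alone (adjusted p = 3.67e-08 and adjusted p = 0.509 with an estimated correlation), Col15a1 at -0.50 ± 0.16, Col6a3 at -0.47 ± 0.16 and Col3a1 at -0.43 ± 0.20. Matrix glycoproteins and proteoglycans (-0.26 over 23, adjusted p = 0.000363 and adjusted p = 0.67 with an estimated correlation) had Nid1 at -0.34 ± 0.17 and Sparc at -0.31 ± 0.19. The PAPP-A and IGF axis had a median of -0.31 over 15 members (adjusted p = 0.00174 and adjusted p = 0.612 with an estimated correlation), Pappa itself at -0.70 ± 0.29, Igf1 at -0.60 ± 0.29 and Igfbp5 at -0.77 ± 0.41. Collagen processing and crosslinking (-0.15 over 17, adjusted p = 0.00844 and adjusted p = 0.696 with an estimated correlation, Loxl1 at -0.44 ± 0.22) was lower. Lower medians were also those of mesenchymal and fibroblast markers (-0.16 over 17, adjusted p = 0.0157 and adjusted p = 0.65 with an estimated correlation, Pdgfra at -0.35 ± 0.19 and Thy1 at 0.99 ± 0.43). Lipogenesis was lower in heart (-0.33 over 11, adjusted p = 0.0288 and adjusted p = 0.763 with an estimated correlation, Mlxipl at -1.20 ± 0.50), with an edgeR median of -1.421. Ribosomal proteins (0.14 over 21, adjusted p = 3.06e-05 and adjusted p = 0.65 with an estimated correlation, Rpl11 at 0.28 ± 0.14) were higher. ER stress genes were higher (0.17 over 11, adjusted p = 0.0234 and adjusted p = 0.65 with an estimated correlation, Pdia6 at 0.24 ± 0.11 and Atf4 at -0.14 ± 0.09). So were cell cycle genes (0.85 over 5, adjusted p = 0.0026 and adjusted p = 0.612 with an estimated correlation, Mki67 at 2.58 ± 0.97). In all of these lists 0 members passed adjusted over the list alone.

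Of 11252 genes tested in heart 0 passed by edgeR (306 at an unadjusted p under 0.05), by DESeq2 and by limma-voom. Mppe1 (0.51 ± 0.14), Gtpbp1 (0.41 ± 0.13) and the chemokine receptor gene Cxcr4 (1.80 ± 0.55), and Egfr (-0.48 ± 0.12), Mir22hg (-0.65 ± 0.19) and Slc8b1 (-0.71 ± 0.20), had the smallest p values. Without the libraries in doubt, in heart those of mice 22 and 56, low in cardiomyocyte genes, the collagen median was -0.19 (adjusted p = 4.69e-05). The collagen processing (0.01, adjusted p = 0.65), mesenchymal (-0.08, adjusted p = 0.0719), PAPP-A and IGF (-0.12, adjusted p = 0.104), lipogenesis (-0.09, adjusted p = 0.372) and cell cycle (0.06, adjusted p = 0.717) lists were then not called. Leaving out treated mouse 56 alone ended the calls of matrix (-0.10, adjusted p = 0.0655), collagen processing (0.00, adjusted p = 0.856), PAPP-A and IGF (-0.11, adjusted p = 0.0546) and cell cycle (0.10, adjusted p = 0.682) genes. Mesenchymal markers were lost without treated mouse 41 or 56 or control mouse 61 (-0.19 to -0.06, adjusted p = 0.0514 to 0.17), and ER stress genes in 8 of 22 fits. Lipogenesis was lost without control mouse 22 (0.02, adjusted p = 0.919) or 61 or treated mouse 23, 36, 41 or 70. Collagen processing was not called with 2 surrogate variables (-0.11, adjusted p = 0.0672). Mki67 in heart was at 0.14 ± 0.29 and Cxcr4 in heart at 0.58 ± 0.27 without mice 22 and 56.

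In kidney erythroid, macrophage and matrix genes were lower and clock genes of the Dbp and Per phase higher. Erythroid genes had a median of -0.47 over 6 members (adjusted p = 0.000419 and adjusted p = 0.509 with an estimated correlation), Hba-a1 at -0.53 ± 0.20. Macrophage genes had one of -0.60 over 8 (adjusted p = 0.00078 and adjusted p = 0.65 with an estimated correlation), the complement genes C1qb at -0.78 ± 0.29 and C1qa at -0.70 ± 0.28. Matrix glycoproteins (-0.16 over 19, adjusted p = 0.00394 and adjusted p = 0.737 with an estimated correlation) had Fbn1 at -1.14 ± 0.40 and Ogn at -0.47 ± 0.16. Kidney collagens (-0.20 over 16, adjusted p = 0.0257 and adjusted p = 0.767 with an estimated correlation) had Col3a1 at -1.41 ± 0.52, Col1a2 at -0.65 ± 0.29 and Col1a1 at -0.53 ± 0.33. The clock list was at 0.16 over 8 members (adjusted p = 0.0045 and adjusted p = 0.536 with an estimated correlation), Per1 at 0.54 ± 0.21 and Hlf at 0.21 ± 0.10. Lipogenesis was at 0.18 over 11 (adjusted p = 0.0259 and adjusted p = 0.65 with an estimated correlation), Elovl6 at 0.55 ± 0.18 and Fasn at 0.79 ± 0.39. Beside it, the mean of brown and beige fat genes was higher in treated kidneys by 0.67 (permutation test, p = 0.0164, adjusted p = 0.443) and that of adipocyte genes by 0.32 (permutation test, p = 0.448). By camera neither list was called, brown and beige fat at a median of 0.11 over 5 members (adjusted p = 0.311). The adipocyte median was -0.13 over 9 members (camera, adjusted p = 0.532), so the direction of adipocyte genes depended on the measure. Adjusted over the list alone 0 members of these 6 lists passed, and 0 of 11476 genes passed by edgeR (485 at an unadjusted p under 0.05), DESeq2 or limma-voom. Aacs, which encodes acetoacetyl-CoA synthetase (0.51 ± 0.11), Slc22a26 (1.13 ± 0.31) and Prob1 (0.73 ± 0.20), and Aoah (-0.40 ± 0.09), Tsnax (-0.30 ± 0.08) and Agfg2 (-0.44 ± 0.11), had the smallest p values. In controls Col3a1 stood at 19.25 ± 28.2 CPM (SD, n = 12) and in treated mice at 7.17 ± 3.09 CPM (n = 10), so the spread between control mice exceeded the difference.

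The kidney library of control male mouse 37 had the highest mean of the 22 for collagens (3.82 log2 CPM of all counts). On the other scale, of counts outside the abundant features, it was also highest for adipocyte (6.77), macrophage (5.25), cell cycle (3.01) and pancreas acinar (1.40) genes. Control female mouse 3 came second for collagens (3.32) and macrophage genes (4.71). Without mouse 37 the kidney collagens (-0.07, adjusted p = 0.497) and matrix genes (-0.07, adjusted p = 0.0893) were not called, and the macrophage median was -0.39 (adjusted p = 0.024). Col3a1 in kidney was then at -0.82 and Fbn1 in kidney at -0.59. Without mouse 3 the collagens (-0.12, adjusted p = 0.501) and matrix genes (-0.14, adjusted p = 0.133) were not called either. The collagens were also lost without control mouse 11 or 22 or treated mouse 36 or 62 (-0.21 to -0.17, adjusted p = 0.052 to 0.0808), and lipogenesis in 8 of 22 fits.

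In liver collagens and matrix genes were lower. Adjusted over the list alone 6 of 12 collagens fell and 6 did not pass (median -0.40, adjusted p = 2.77e-05 and adjusted p = 0.509 with an estimated correlation). Among the former were Col1a2 (-1.18 ± 0.42), Col3a1 (-1.11 ± 0.38), Col6a1 (-0.98 ± 0.29) and Col6a3 (-0.95 ± 0.29). Matrix glycoproteins and proteoglycans had a median of -0.29 over 13 members with 0 passing (adjusted p = 3.67e-08 and adjusted p = 0.242 with an estimated correlation), Nid1 at -0.45 ± 0.16, Fbn1 at -0.79 ± 0.28 and Lum at -0.78 ± 0.30. Endothelial genes (-0.18 over 7, adjusted p = 0.0234 and adjusted p = 0.536 with an estimated correlation, Kdr at -0.18 ± 0.10) were lower. Mesenchymal and fibroblast markers were lower (-0.08 over 10, adjusted p = 0.0413 and adjusted p = 0.569 with an estimated correlation, Pdgfra at -0.56 ± 0.22 and Pdgfrb at -0.47 ± 0.21). Heat shock genes were higher (0.15 over 7, adjusted p = 0.0353 and adjusted p = 0.65 with an estimated correlation, Hspd1 at 0.21 ± 0.10), and 0 members of these 3 lists passed adjusted over the list alone. Endothelial genes were not called without control mouse 37 or 68 or treated mouse 41, 58 or 70 (-0.19 to -0.12, adjusted p = 0.0544 to 0.117). Of the 22 fits without 1 mouse, 11 lost the mesenchymal list and 9 the heat shock list, and with 2 surrogate variables the mesenchymal list had an adjusted p of 0.0502. Of 8897 genes 0 passed by edgeR (317 at an unadjusted p under 0.05), DESeq2 or limma-voom. The smallest p values were those of the cytochrome P450 genes Cyp2c69 (1.30 ± 0.31) and Cyp2c40 (1.12 ± 0.32), close paralogs that can share reads, and of Rarres1 (0.57 ± 0.15). With lower means they were those of Scd2 (-0.60 ± 0.14), Gsn (-0.99 ± 0.24) and Reln (-0.37 ± 0.10). Without any count filter, or without treated mouse 9, 1 gene passed, the P450 gene Cyp3a44, which was chosen after its values were seen.

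In lung genes of hepatocytes and plasma proteins were lower in treated mice, with lipogenic, ribosomal and macrophage genes, and clock genes were higher. All 7 hepatocyte genes tested fell when adjusted over the list alone (median -2.07, adjusted p = 6.5e-05 and adjusted p = 0.612 with an estimated correlation). Among them were Cps1 (-2.20 ± 0.68), Ttr (-2.25 ± 0.70), Ahsg (-2.11 ± 0.66) and Apoa1 (-2.07 ± 0.74). Of the acute phase genes (-2.11 over 5, adjusted p = 0.0209 and adjusted p = 0.612 with an estimated correlation) the fibrinogen chains Fga (-2.41 ± 0.71), Fgg (-2.20 ± 0.67) and Fgb (-2.17 ± 0.69) fell and 2 did not pass. These genes were low in both arms, Fga at 7.81 ± 8.90 CPM (SD, n = 12) in controls, and usable depth was lower in treated lungs by -0.71 on the log2 scale. In lipogenesis (-0.32 over 12, adjusted p = 0.000539 and adjusted p = 0.65 with an estimated correlation) the desaturase gene Scd1 fell (-1.19 ± 0.37) adjusted over the list alone and 11 members did not pass, Acly at -0.42 ± 0.15. Adipocyte means were over 8 log2 CPM in 2 lung libraries, both of control males, mouse 68 (9.37) and mouse 37 (8.05), and reached 6.24 in treated mice. Scd1 stood at 415.3 ± 486.1 CPM (SD, n = 12) in control and 170.7 ± 34.72 CPM (n = 10) in treated lungs, and Scd1 in lung was at -0.72 without mouse 37 and -1.13 without mouse 68. The lipogenesis median was -0.15 (adjusted p = 0.00719) and -0.18 (adjusted p = 0.00325) in those fits. In the clock list (0.26 over 9, adjusted p = 0.0022 and adjusted p = 0.612 with an estimated correlation) Per1 rose (0.61 ± 0.17) and 8 members did not pass, Per2 at 0.39 ± 0.20.

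The 11 other lung lists were lower with 0 members passing adjusted over the list alone. Ribosomal proteins had a median of -0.16 over 22 members (adjusted p = 1.46e-05 and adjusted p = 0.65 with an estimated correlation), Rps18 at -0.53 ± 0.19. Collagen processing (-0.15 over 18, adjusted p = 0.00453 and adjusted p = 0.584 with an estimated correlation) had Pcolce at -0.32 ± 0.10 and Lox at -0.62 ± 0.26. Matrix glycoproteins (-0.22 over 24, adjusted p = 0.00607 and adjusted p = 0.65 with an estimated correlation) had Sparc at -0.62 ± 0.23. Lung collagens (-0.14 over 16, adjusted p = 0.0259 and adjusted p = 0.767 with an estimated correlation) had Col18a1 at -0.71 ± 0.28 and Col3a1 at -0.67 ± 0.35. Macrophage genes (-0.34 over 10, adjusted p = 0.00628 and adjusted p = 0.65 with an estimated correlation) had C1qb at -1.03 ± 0.44. Erythroid genes (-0.45 over 5, adjusted p = 0.00678 and adjusted p = 0.65 with an estimated correlation) had Hbb-bt at -0.38 ± 0.24. B cell genes (-0.39 over 8, adjusted p = 0.0215 and adjusted p = 0.72 with an estimated correlation) had Cr2 at -0.83 ± 0.37. ER stress genes (-0.14 over 12, adjusted p = 0.0144 and adjusted p = 0.691 with an estimated correlation) had Calr at -0.23 ± 0.11. Interferon response genes (-0.17 over 11, adjusted p = 0.0239 and adjusted p = 0.696 with an estimated correlation) had Ifit3 at -0.42 ± 0.16. Oxidative phosphorylation (-0.16 over 17, adjusted p = 0.027 and adjusted p = 0.861 with an estimated correlation) had Cox5b at -0.36 ± 0.28. Adipocyte genes (-1.28 over 7, adjusted p = 0.0218 and adjusted p = 0.741 with an estimated correlation) had Cidec at -2.19 ± 1.15.

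By edgeR 0 of 12886 lung genes passed (887 at an unadjusted p under 0.05), and DESeq2 and limma-voom called 0. Among the genes with the smallest p values were Ajuba (0.41 ± 0.09) and Furin (0.31 ± 0.08), and Ugt1a6b (-1.62 ± 0.37), Pbdc1 (-0.61 ± 0.15) and Snx6 (-0.35 ± 0.09), at an adjusted p of 0.713. Without the libraries in doubt, in this tissue the one labelled lung of control mouse 68, the collagen median was 0.01 (adjusted p = 0.657). The matrix (-0.16, adjusted p = 0.0718), adipocyte (-0.38, adjusted p = 0.325), B cell (-0.16, adjusted p = 0.245), oxidative phosphorylation (-0.05, adjusted p = 0.451) and ER stress (-0.09, adjusted p = 0.0788) lists were then not called. Collagens were also lost without control mouse 4 or 37 or treated mouse 41 or 58 (-0.13 to -0.09, adjusted p = 0.0526 to 0.0697), and adipocyte genes without control mouse 37 (-0.46, adjusted p = 0.211). The lung library of mouse 37 was second to that of mouse 68 in adipocyte genes (8.05 log2 CPM outside the abundant features). It was also second in collagens (4.44 log2 CPM of all counts). Interferon response genes were lost without control mouse 11 or 22 or treated mouse 33 (-0.13 to -0.08, adjusted p = 0.081 to 0.213). Without treated mouse 33 acute phase genes were not called (-1.92, adjusted p = 0.0718), and without control mouse 18 (-0.08, adjusted p = 0.0797) or treated mouse 56 (-0.10, adjusted p = 0.0531) ER stress genes were not. Of the 22 fits without 1 mouse, 6 lost the B cell list and 9 oxidative phosphorylation. With 2 surrogate variables the collagen and oxidative phosphorylation lists reversed, to 0.07 and 0.04. Matrix (-0.03, adjusted p = 0.448), collagen processing (-0.04, adjusted p = 0.242), adipocyte (-0.23, adjusted p = 0.608), macrophage (-0.01, adjusted p = 0.905) and B cell (0.00, adjusted p = 0.905) genes were then not called. Nor were ribosomal proteins (-0.04, adjusted p = 0.104), ER stress (-0.03, adjusted p = 0.77) or acute phase (-1.78, adjusted p = 0.0947) genes.

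In skin collagens were lower in treated mice, together with cell cycle and immediate early genes. All 14 collagens tested had a lower mean, and adjusted over the list alone 7 fell and 7 did not pass (median -0.52, adjusted p = 8.26e-11 and adjusted p = 0.509 with an estimated correlation). Examples were Col1a2 (-0.83 ± 0.24), Col6a2 (-0.81 ± 0.22), Col12a1 (-0.70 ± 0.21) and Col18a1 (-0.58 ± 0.18), with Col1a1 at -0.52 ± 0.35. Of the immediate early genes (-0.32 over 9, adjusted p = 0.00185 and adjusted p = 0.612 with an estimated correlation) Egr1 (-0.66 ± 0.21), Junb (-0.49 ± 0.17) and Fos (-0.99 ± 0.36) fell adjusted over the list alone and 6 did not pass. Cell cycle genes (-0.25 over 12, adjusted p = 0.00077 and adjusted p = 0.569 with an estimated correlation, Ccna2 at -0.65 ± 0.23 and Mki67 at -0.53 ± 0.25) were lower with 0 members passing. Keratinocyte genes were lower (-0.52 over 10, edgeR median -0.145, adjusted p = 0.00689 and adjusted p = 0.696 with an estimated correlation, Krt1 at -0.62 ± 0.47), as were ribosomal proteins (-0.18 over 22, adjusted p = 0.0391 and adjusted p = 0.877 with an estimated correlation, Rps18 at -0.21 ± 0.17). So were matrix glycoproteins (-0.31 over 15, adjusted p = 0.0398 and adjusted p = 0.743 with an estimated correlation, Fn1 at -0.61 ± 0.20), and in these 3 lists 0 members passed adjusted over the list alone. By edgeR 0 of 9894 genes passed (316 at an unadjusted p under 0.05), limma-voom called 0 and DESeq2 called 2, Hist2h2aa2 and Rps12-ps3, each at a count of 0 in 19 of the 22 libraries. Both were chosen after their values were seen. Slc25a24 (0.54 ± 0.16), Zfp330 (0.36 ± 0.11) and Siae (0.63 ± 0.20), and Col6a2, Tacc3 (-0.79 ± 0.22) and Atad2 (-0.53 ± 0.15), had the smallest p values. Without the libraries in doubt, in skin that of mouse 36 with 33377 usable counts, the collagen median was -0.59 (adjusted p = 1.29e-10), the keratinocyte list was at 0.01 (adjusted p = 0.70) and the ribosomal list at -0.01 (adjusted p = 0.91). The ribosomal and matrix lists were each lost in 8 of the 22 fits without 1 mouse. Hair follicle genes were not called in skin (adjusted p = 0.454), but all 8 tested had a lower mean by edgeR (median -1.32), while the median on the voom scale was -0.18. Their mean ran from 2.58 to 8.51 log2 CPM (median 5.06) in controls, highest in mouse 71, and from 1.32 to 6.06 (median 4.48) in treated mice. Without control mouse 71 the matrix (-0.15, adjusted p = 0.225) and ribosomal (-0.17, adjusted p = 0.0768) lists were not called. With 2 surrogate variables the keratinocyte median was 0.04, and the ribosomal (-0.01, adjusted p = 0.978) and matrix (-0.32, adjusted p = 0.0904) lists were not called.

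In spleen erythroid genes were lower in treated mice, and MHC class II and matrix genes were higher. Adjusted over the list alone 6 of the 7 erythroid genes fell and 1 did not pass (median -1.15, adjusted p = 3.67e-08 and adjusted p = 0.509 with an estimated correlation). Among the former were the red cell membrane gene Slc4a1 (-1.91 ± 0.57) and the haem synthesis gene Alas2 (-1.03 ± 0.37). Slc4a1 stood at 22.6 ± 32.1 CPM (SD, n = 12) in controls, with an SD of 5.38 CPM in treated mice. Cell cycle genes (-0.18 over 15, adjusted p = 0.000298 and adjusted p = 0.65 with an estimated correlation, Ccnb1 at -0.45 ± 0.23) were lower. Oxidative phosphorylation was lower (-0.07 over 17, adjusted p = 0.01 and adjusted p = 0.509 with an estimated correlation, Sdhc at -0.24 ± 0.11). MHC class II (0.06 over 7, adjusted p = 0.0106 and adjusted p = 0.65 with an estimated correlation, H2-Aa at 0.13 ± 0.06) was higher. So were matrix glycoproteins (0.14 over 21, adjusted p = 0.0146 and adjusted p = 0.67 with an estimated correlation, Thbs1 at 0.57 ± 0.20 and Postn at -0.34 ± 0.18), and in these 4 lists 0 members passed adjusted over the list alone. The spleen library of control male mouse 45 had a pancreas acinar mean of 8.79 log2 CPM, against a control median of 0.39 and a treated maximum of 1.80, and without it the matrix list was not called (0.12, adjusted p = 0.0739). That list was also lost without control mouse 11 or 55 or treated mouse 62 (0.08 to 0.12, adjusted p = 0.06 to 0.263), and MHC class II without treated mouse 9 (0.04, adjusted p = 0.0557). Collagens were not called in spleen (0.09 over 14, adjusted p = 0.21), Col5a2 at 0.28 ± 0.14. They were called higher with 2 surrogate variables (0.16, adjusted p = 0.00355). Of 11978 genes 0 passed by edgeR (633 at an unadjusted p under 0.05) or limma-voom, and DESeq2 called 1, Gm11808, at a count of 0 in 18 libraries and chosen after its values were seen. The smallest p values were those of Dnm3 (0.77 ± 0.17), the integrin gene Itgb3 (0.39 ± 0.10) and Zdhhc20 (0.30 ± 0.08), and, with lower means, Dynlrb1 (-0.46 ± 0.10), Bsg (-0.33 ± 0.07) and Bpgm (-0.91 ± 0.24), a glycolytic enzyme gene of red cells.

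In subscapular fat skeletal muscle genes were higher in treated mice and interferon response genes lower. The muscle list had a median of 2.90 over 12 members with 0 passing adjusted over the list alone (adjusted p = 3.06e-05 and adjusted p = 0.65 with an estimated correlation). By edgeR, which gave the member values, the median was only 0.965. Examples were the myosin genes Myh2 at 1.86 ± 1.55 and Myh1 at 1.25 ± 1.43 and myoglobin (Mb) at 1.34 ± 1.15. Mean muscle expression ran from 1.05 to 12.19 log2 CPM in controls and from 0.87 to 12.34 in treated mice, and 8 of the 22 libraries resembled another tissue more than their own. Smooth muscle genes, among them Des, which skeletal muscle also expresses (1.08 ± 1.00), were at 0.27 over 8 (adjusted p = 0.0391 and adjusted p = 0.696 with an estimated correlation), Synpo2 at 0.82 ± 0.47. Glucocorticoid targets were at 0.28 over 10 (adjusted p = 0.0143 and adjusted p = 0.612 with an estimated correlation), Sgk1 at 0.44 ± 0.29. Lower were interferon response genes (-0.50 over 10, adjusted p = 8.17e-05 and adjusted p = 0.509 with an estimated correlation, Irf7 at -0.62 ± 0.32 and Bst2 at -0.49 ± 0.23) and cell cycle genes (-0.74 over 6, adjusted p = 0.00109 and adjusted p = 0.569 with an estimated correlation, Pcna at -0.42 ± 0.18). Macrophage genes were lower (-0.39 over 9, adjusted p = 0.00678 and adjusted p = 0.732 with an estimated correlation, C1qc at -0.57 ± 0.26). So was MHC class II (-0.27 over 7, adjusted p = 0.029 and adjusted p = 0.753 with an estimated correlation, Ciita at -0.89 ± 0.49). In ribosomal proteins (-0.09 over 22, adjusted p = 0.00794 and adjusted p = 0.763 with an estimated correlation) Rpl10a fell adjusted over the list alone (-0.49 ± 0.12), and in all other lists of this tissue 0 members passed. By edgeR 0 of 11019 genes passed (261 at an unadjusted p under 0.05), as by DESeq2 and limma-voom. Pla2g12a (0.74 ± 0.24), Socs6 (0.34 ± 0.12) and Cldnd1 (0.37 ± 0.13), and the iron exporter gene Slc40a1 (-0.89 ± 0.22), Rpl10a and Dck (-0.79 ± 0.20), had the smallest p values. Collagens were not called (-0.03 over 17, adjusted p = 0.708), Col3a1 at -0.33 ± 0.40. The muscle (0.35, adjusted p = 0.0846), smooth muscle (0.19, adjusted p = 0.299) and MHC class II (-0.24, adjusted p = 0.0672) lists were not called with 2 surrogate variables.

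The subscapular fat library of control female mouse 20 had a B cell mean of 7.64 log2 CPM, where the next highest was 1.90, and the highest cell cycle mean (3.74). It was the library least like the others of its tissue (mean r = 0.6258). Without it MHC class II (-0.12, adjusted p = 0.216), ribosomal proteins (-0.02, adjusted p = 0.423), smooth muscle (0.09, adjusted p = 0.301) and glucocorticoid targets (0.17, adjusted p = 0.0646) were not called, and Ciita in subscapular fat was at -0.33. Too few cell cycle genes passed the count filter for that list to be tested without it. The interferon median was then -0.45 (adjusted p = 0.000724). Macrophage genes were lost without treated mouse 62 (-0.19, adjusted p = 0.176) or 70 (-0.26, adjusted p = 0.0848) or control mouse 71 (-0.26, adjusted p = 0.058). Ribosomal proteins were also lost without treated mouse 41 (-0.07, adjusted p = 0.0547) or control mouse 45 (-0.07, adjusted p = 0.0587). So were glucocorticoid targets without treated mouse 36 (0.22, adjusted p = 0.0601) or 41 (0.27, adjusted p = 0.0514). MHC class II was lost in 8 and smooth muscle in 12 of the 22 fits without 1 mouse.

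Across the tissues the collagen list was called lower in 7 of 9 and higher in 0. With an estimated correlation 0 of the 7 calls held (adjusted p = 0.509 to 0.767). With 2 surrogate variables the marrow call was lost (-0.15), lung reversed (0.07) and spleen was called higher (0.16). The lung call also ended without control mouse 68 (0.01) and the kidney call without control mouse 37 (-0.07). The 4 collagens that passed the count filter in every tissue, Col1a1, Col1a2, Col4a1 and Col5a1, were lower by a mean log2 difference of -0.22 when each mouse was given 1 value, its mean over the tissues (permutation test within sex, two-sided, p = 0.0134). Camera on the same values gave p = 7.67e-05, and p = 0.0221 with an estimated correlation. Each tissue's own tested collagens, averaged per mouse, stood at 0.12 ± 0.18 (SD, n = 12) in control and -0.14 ± 0.16 (n = 10) in treated mice relative to the tissue mean, a difference of -0.25 (permutation test, p = 0.0038) with all 10 treated mice below the control median. Among the 26 lists with such a value in 5 or more tissues this did not pass adjustment (adjusted p = 0.0988), nor did the PAPP-A and IGF axis (-0.12, adjusted p = 0.138), matrix glycoproteins (-0.16, adjusted p = 0.164) or erythroid genes (-0.35, adjusted p = 0.26). By camera on the per-mouse values, clock genes of the Dbp and Per phase were higher (median 0.07 over 6 members, adjusted p = 0.000512 and adjusted p = 0.571 with an estimated correlation). Lipogenic genes (-0.19 over 7) and ribosomal proteins (-0.07 over 21) were lower, each at adjusted p = 0.0127 and adjusted p = 0.62 with an estimated correlation. In the permutation test of each tissue's own members these 3 lists did not pass, the clock list at 0.07 (p = 0.419, adjusted p = 0.681), lipogenesis at -0.21 (p = 0.151, adjusted p = 0.509) and ribosomal proteins at -0.07 (p = 0.211, adjusted p = 0.55).

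**Figure D3:**
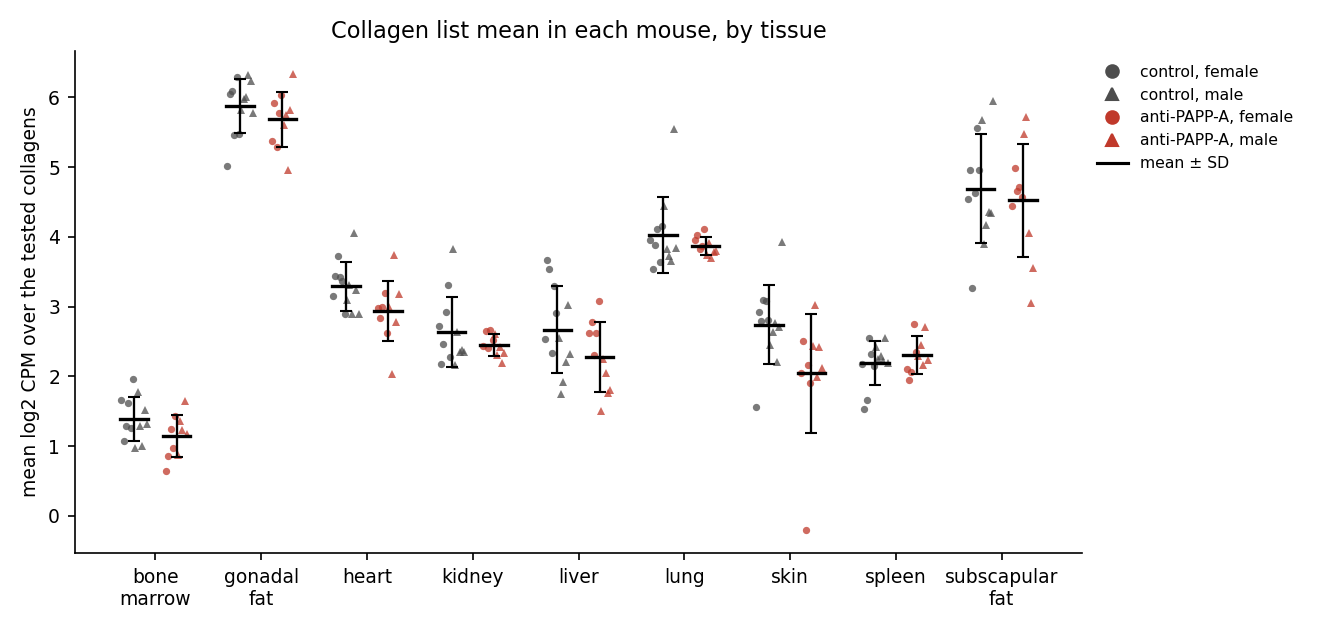
Mean log2 CPM over the tested collagens for each mouse, by tissue. Points are mice (grey control, red anti-PAPP-A, circles female, triangles male) and black lines the mean ± SD of each arm, and the list was called lower in 7 tissues with a preset correlation and in 0 with an estimated one (adjusted p = 0.509 to 0.767).

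Igfbp5 had a lower mean in treated mice in all 8 tissues where it was tested, from a log2 fold change of -0.15 in kidney to -1.56 in marrow, with only marrow passing. Igfbp5 in lung was at 0.08 without control mouse 68. With all lung libraries it was at 0.52 in females and -0.90 in males, and only 3 treated mice lay below the control median there. Averaged over the 8 tissues per mouse Igfbp5 was 4.41 ± 0.31 log2 CPM (SD, n = 12) in control and 3.81 ± 0.27 (n = 10) in treated mice, and all 10 treated mice lay below the control median (difference -0.60, permutation test, p = 0.00029). Without marrow the difference was -0.47 (permutation test, p = 0.00263). Without the 5 libraries in doubt it was -0.48 (permutation test, p = 0.00093), and without both -0.34 (permutation test, p = 0.0192) with 7 of 10 treated mice below the control median. Col1a1 (chromosome 11 from 94936224 to 94953042) and Col1a2 (chromosome 6 from 4504814 to 4541544) had lower means in 8 of 9 tissues and Col3a1 (chromosome 1 from 45311538 to 45349706) in 7 of 8, spleen being the exception. In lung the sexes went opposite ways, Col1a1 at 0.58 in females and -0.69 in males (-0.05 ± 0.29 in both) and Col1a2 at 0.26 and -0.75. Neither interaction passed (edgeR, adjusted p = 0.60 and 0.635). The lung collagen mean was 5.54 log2 CPM in control male mouse 68, a library in doubt, and 4.44 in control male mouse 37. Other control males lay at 3.65 to 3.83 and treated males at 3.70 to 3.91. With such libraries among the control males, the opposite signs cannot be read as a difference between the sexes. Igf1 had a lower mean in 6 of 8 tissues and Igfbp4, the other binding protein that PAPP-A cleaves, in 6 of 9, from -0.41 in gonadal fat to 0.17 in liver. Pappa (chromosome 4 from 65124174 to 65357509) passed the count filter in 4 tissues, at -0.70 ± 0.29 in heart, 0.22 ± 0.19 in kidney, 0.04 ± 0.20 in lung and -0.03 ± 0.30 in skin. Apart from Igfbp5 in marrow none of these genes passed over all genes in any tissue.

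**Figure D4:**
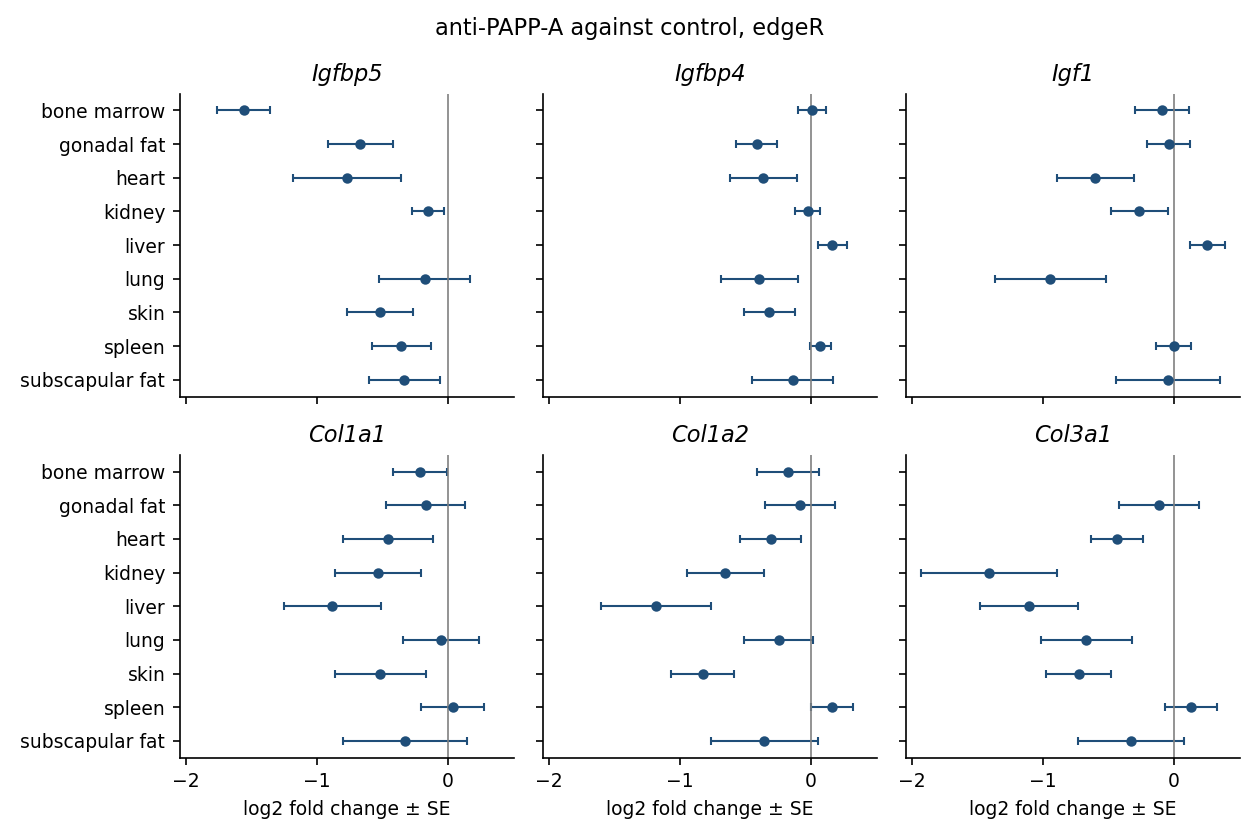
Log2 fold change of anti-PAPP-A against control (points) with its SE (bars) from edgeR for 6 genes fixed before the data were examined, by tissue. Igfbp5 lies left of 0 in all 8 tissues tested, though Igfbp5 in lung is at 0.08 without control mouse 68. Col1a1 and Col1a2 lie left of 0 in 8 of 9, Col1a1 in lung at only -0.05 with that mouse included.

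**Figure D5:**
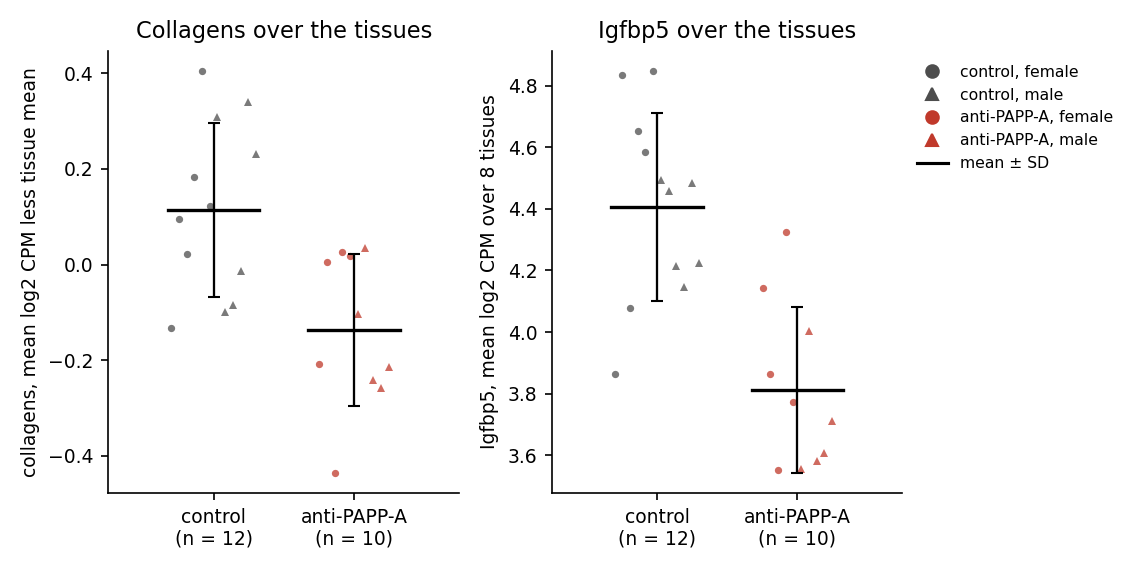
Each mouse's mean over the tissues for the collagens (log2 CPM less the tissue mean) and for Igfbp5 (log2 CPM over 8 tissues). Points are mice (grey control, red anti-PAPP-A, circles female, triangles male) and black lines the mean ± SD, at 0.12 and -0.14 for collagens and 4.41 and 3.81 for Igfbp5.

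Gene by gene over the tissues, the collagens Col5a1 (-0.26 ± 0.07, SE) and Col1a2 (-0.32 ± 0.11) and the binding protein gene Igfbp4 (-0.14 ± 0.05) had lower means in treated mice, and Ptpn22, a lymphocyte phosphatase gene, a higher one (0.27 ± 0.08). None passed, with an adjusted p of 0.854 for each. With each mouse's mean over 9 tissues tested by limma, 0 of 6458 genes passed (247 at an unadjusted p under 0.05), and limma-voom with the mouse as a replicate block called 0 (225 at an unadjusted p under 0.05, lowest adjusted p = 0.143). Cmtr1 (-0.22 ± 0.06) had the smallest p in the test of each mouse's mean, and the clock gene Per1, chosen after its values were seen, had it with the block (0.37, p = 2.21e-05, adjusted p = 0.143). No gene was called in the same direction in 3 or more tissues by edgeR or limma-voom. The count shared by 2 or more tissues was 0 as well.

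Macrophage genes were called higher in gonadal fat and lower in kidney, lung and subscapular fat, and erythroid genes lower in gonadal fat, kidney, lung and spleen, at the preset correlation only. With an estimated correlation 0 of these held (adjusted p = 0.425 to 0.732). The gonadal fat macrophage call ended without treated mouse 58 (0.12, adjusted p = 0.0682) and with 2 surrogate variables (0.06, adjusted p = 0.799). The difference between tissues was tested gene by gene and not for lists. With limma-voom, 0 of 6458 genes had a treatment effect that differed between tissues (229 at an unadjusted p under 0.05, lowest adjusted p = 0.888), and with the mouse as a replicate block 0 did (248 at an unadjusted p under 0.05, lowest adjusted p = 0.795). Clic1, at -0.71 in subscapular fat and 0.36 in gonadal fat, and Ptpn6, at -0.88 and 0.57, had the smallest p values. They were chosen after their values were seen.

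The effect of treatment was compared between the sexes in each tissue. In spleen 1 feature passed, the transcript CCDS15327 (uc033fmc.1), with a male minus female difference of -4.99 in log2 fold change (edgeR, adjusted p = 0.0429), from 4.60 in females and -0.39 in males. Its counts ran from 0 to 41 per library, DESeq2 called it with 1 other feature (Gm12896), and limma-voom called 0. It was lost in 17 of the 22 fits that left out 1 mouse, the other 5 being those without control mouse 20, 61 or 68 or treated mouse 6 or 62. The other tissues had 0 interactions by edgeR and by limma-voom, with 585 genes at an unadjusted p under 0.05 in marrow, 273 in gonadal fat, 650 in heart, 504 in kidney, 296 in liver, 1009 in lung, 253 in skin and 165 in subscapular fat, against 291 in spleen. DESeq2 called Cyp2c40 in liver, Pck1 and Ucp1 in lung, Acvr1c in heart, Myh2 in skin, and Ighv1-26 and CH1B1_MOUSE in gonadal fat, and 0 in marrow, kidney and subscapular fat. Ucp1 belongs to the brown and beige fat list and Myh2 to the skeletal muscle list. Skeletal muscle means in skin reached 8.89 log2 CPM in control and 8.72 in treated libraries, against medians of 1.55 and 1.61. Adipocyte means reached 9.37 in control lungs and 9.24 in control hearts, against medians of 3.74 and 3.72. Whether libraries that hold other tissue gave the calls in lung, heart and skin was not tested. Cyp2c40, a P450 gene of sex-biased expression in mouse liver, was at 2.50 in males with an overall log2 fold change of 1.12 (interaction p = 1.82e-05, adjusted p = 0.162). The features called by DESeq2 were chosen after their values were seen.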

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

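Of the tests below, those of marrow stromal genes, of the abundant features, of Igfbp5 over the tissues, of muscle in subscapular fat, of the collagens with each tissue's own members or without the libraries in doubt, and of gene lists without 1 mouse were chosen only after the result was seen.

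In marrow Igfbp5 was the 1 gene called. In 6 of 100 regroupings of the mice within sex, the real one included, as many genes were called (real 1, highest other 30), so chance is not excluded for the count. The log2 fold change was -1.555 without the abundant features, and the highest adjusted p on leaving out 1 mouse was 0.00266, which argues against those features or a single mouse as the cause. The mean log2 fold change over 17 other stromal and bone genes was -0.036 ± 0.076 (SE over the genes, not over mice), so their estimates did not fall as a set. That SE takes the genes as independent and does not measure the spread between mice. Of the 17, 7 had lower means, among them Lepr (-0.53 ± 0.21), Ibsp (-0.86 ± 0.31) and Cxcl12 (-0.30 ± 0.16). Runx2 (0.27 ± 0.09) and Dmp1 (0.45 ± 0.17) had higher ones. The set mixes kinds of cell, so its mean cannot decide on a loss of the cells that express Igfbp5, which may contribute. Over the tissues the difference in Igfbp5 had a permutation p of 0.00029, and without the libraries in doubt it was -0.483 (permutation p = 0.00093). That average includes marrow, which held none of these libraries. Without marrow the difference was -0.473, and without both -0.336 (permutation p = 0.0192), with 7 of 10 treated mice below the control median. This argues against these libraries as the whole cause, but they may contribute. Libraries that may hold added tissue but kept their own markers, such as lung of control mouse 37, were not left out. An effect of the antibody on Igfbp5 transcript stays a hypothesis.

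The collagen list was called lower in 7 tissues, a number reached in 1 of 100 regroupings, the real one (highest other 4). That is under 0.05, but no adjustment was made over the numbers tested in this way, so chance is not excluded. With an estimated correlation 0 of the 7 held (adjusted p = 0.509 to 0.767). With 2 surrogate variables spleen was called higher (0.163), marrow was lost (-0.146) and lung reversed (0.072). The marrow, kidney and lung calls ended in 6, 6 and 5 of the fits that left out 1 mouse, and the per-mouse difference in each tissue's own collagens did not pass over 26 lists (adjusted p = 0.0988). Each tissue's own collagens, less the mean of mesenchymal markers, were lower in treated mice (-0.183, permutation p = 0.00958). The collagens thus fell by more than those markers. The marker list mixes kinds of cell, in heart with Pdgfra lower and Thy1 higher, so this test cannot decide on fewer stromal cells. With depth as a covariate the difference in these collagens was -0.248 (permutation p = 0.00247), and without the 5 libraries in doubt -0.188 (permutation p = 0.0139). This argues against depth or these 5 libraries as the whole cause. The rule for doubt takes only libraries low in their own markers or in genes detected, so libraries with added tissue could stay in. Among those kept were control libraries high in collagens, kidney of mice 37 (3.82 log2 CPM) and 3 (3.32) and lung of mouse 37 (4.44). Uneven dissection was thus not tested for the collagens. An effect of the antibody on collagen transcripts stays a hypothesis, and a change in the kind of stromal cell was not tested.

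Skeletal muscle genes were higher in treated subscapular fat. Mean muscle expression was over 8 on the log2 scale in 6 of 12 control and 7 of 10 treated libraries (Fisher's exact test, p = 0.415), and under 3 in 5 and 2. Such a split in both arms is consistent with adjoining muscle taken with some samples. A biological difference in muscle content was not tested.

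Gene list calls numbered 73, reached in 3 of 100 regroupings (highest other 76, median of the others 55). That is under 0.05, but no adjustment was made over the numbers tested in this way, so chance is not excluded. With an estimated correlation, or by permutation of list means, 0 of the 243 list and tissue pairs passed. For the counts of genes in the 8 tissues other than marrow the real value was 0, which all 100 regroupings reach. The highest other was 80 in gonadal fat, 63 in heart, 5 in kidney, 2 in liver, 0 in lung, 215 in skin, 13 in spleen and 6 in subscapular fat. For interactions the real value was also 0 outside spleen, reached in all 100, with highest others of 500 in marrow, 5 in gonadal fat, 32 in heart, 3 in kidney, 14 in liver, 1 in lung, 8 in skin and 1446 in subscapular fat. In spleen 6 of 100 gave as many interactions (real 1, highest other 105). All 100 also reached the 0 genes over the tissues (highest other 0), the 0 that differ between tissues (383) and the 0 shared by 3 or more tissues (0). Single regroupings called many genes, among them those named for skin, for marrow, and for interactions in marrow, spleen and subscapular fat. Why they did so was not tested.

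The interaction of CCDS15327 in spleen passed at an adjusted p of 0.0429 by edgeR.

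Of 130 sets of values of the 10 treated mice of a tissue tested for a sample far from the others, 24 had one, and chance marks about 1 in 20. Values are the gap to the nearest sample over the range. In gonadal fat mouse 58 lay lowest in its tissue markers (0.578), Igfbp4 (0.573), Igf1 (0.548) and Igfbp5 (0.496) and highest in Stk10 (0.506), and mouse 9 lowest in Med9 (0.515). In heart mouse 56 lay lowest in its tissue markers (0.772) and highest in Gtpbp1 (0.497) and Cxcr4 (0.768), and mouse 9 lowest in Pappa (0.522). In skin mouse 36 lay lowest in depth (0.685), tissue markers (0.679), the collagen mean (0.656), Slc25a24 (0.776), Siae (0.632), Col6a2 (0.604), Tacc3 (0.62), Atad2 (0.88) and Igfbp5 (0.665). Mouse 6 lay lowest in kidney Prob1 (0.476) and spleen Igf1 (0.556) and highest in spleen Col1a1 (0.696) and Col1a2 (0.532), and mouse 58 highest in subscapular fat Cldnd1 (0.487).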

How the results depend on the processing

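Fits without the libraries in doubt, without the abundant features, with quality weights, of gene lists without 1 mouse, with each tissue's own collagens and by permutation of list means were chosen only after results were seen. Igfbp5 in bone marrow was called under each alternative, from -1.68 to -1.47 (adjusted p = 0.000184 to 0.00266) leaving out 1 mouse and from -1.60 to -1.50 (adjusted p = 1.72e-08 to 0.00118) over 8 others. The collagen list over the tissues ran from -0.255 to -0.195 leaving out 1 mouse and was -0.196 (permutation p = 0.027) for the 4 collagens measured in every tissue without the libraries in doubt. Other gene counts moved as follows, and the cause was not tested. With DESeq2 the count was 2 in skin and 1 in spleen, and interactions numbered 2 in gonadal fat, 1 in heart, 1 in liver, 2 in lung, 1 in skin and 2 in spleen. With no low count filter it was 1 in liver, with 2 interactions there (Cyp2c40 and Cyp2b9, named after their values were seen, like Igkv14-126). With limma-voom spleen had 0 interactions. Leaving out 1 mouse gave 0 to 1 genes in liver (1 without treated mouse 9), 0 to 1 interactions in marrow (1, Igkv14-126, without control mouse 71) and liver (1, Cyp2c40, without control mouse 37, control mouse 4 or treated mouse 56), and 0 to 2 in spleen (2 without treated mouse 6, 1 without control mouse 20, 61 or 68 or treated mouse 62, and 0 in the other 17 fits). The mouse as a replicate block left the genes over the tissues and the genes differing between tissues at 0 and changed no call.

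List calls numbered 73 (18 higher, 55 lower), 0 with an estimated correlation and 0 by permutation of list means. Leaving out 1 mouse they numbered 56 (without control mouse 68) to 79, with 35 of the 73 kept in every fit that tested them. Without the libraries in doubt they numbered 56, of which 54 were among the 73. With 2 surrogate variables they numbered 70 (27 higher, 43 lower), of which 47 were, while 20 lists weakened, and the spleen collagens (0.163, adjusted p = 0.00355) and gonadal fat adipocyte genes (0.165, adjusted p = 0.000455) were called higher. The other lists that reversed were not called (adjusted p = 0.339 to 0.799), with medians of 0.062 (macrophage, where the test but not the median turned) and -0.017 (ribosomal proteins) in gonadal fat, 0.072 (collagens) and 0.037 (oxidative phosphorylation) in lung and 0.044 (keratinocyte) in skin. Without the libraries in doubt, or without treated mouse 36, the keratinocyte median in skin was 0.013 (-0.699 to 0.013 leaving out 1 mouse). The causes were not tested. Depth limits all of this, with a median of 1099966.5 usable counts per library. Without the abundant features fewer than 5 collagens were tested in marrow, so that list has no value there.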

Other observations

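In liver the sex-biased P450 genes Cyp2c69 and Cyp2c40 had higher means in treated males, at log2 fold changes of 2.71 and 2.50, with 0.63 and 0.12 in females. Neither passed over all genes tested in the main edgeR fits. The sex by treatment term of Cyp2c40 was called by DESeq2 and in some other alternative fits. Hepatocyte transcripts were lower in treated lung and gonadal fat, with medians of -2.07 and -1.54 over all libraries (adjusted p = 0.612 and 0.545 with an estimated correlation). The medians were -1.87 and -1.32 without the libraries in doubt, a choice made after the data were seen, and no estimated correlation was run on those fits. The permutation test of list means gave -1.682 (p = 0.0328, adjusted p = 0.481) and -0.551 (p = 0.328). Whether these transcripts came from cells of lung and fat or from liver RNA in some libraries was not tested. In gonadal fat Alb was at -0.307 in females and -2.596 in males (interaction p = 0.0771) and Ahsg at -0.077 and -2.494 (interaction p = 0.0925).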
